A study of Salmo salar with 48 samples.

How the data were processed

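RNA sequencing libraries from head kidney, liver and distal intestine of Atlantic salmon in the seawater stage were compared between a control diet and a diet called LAN6 in the titles, which the series design describes as 0.1% hydrolyzed Debaryomyces hansenii, a marine yeast. The labels also sort the fish into groups A and B without saying what they stand for. This gave 12 groups (3 tissues, 2 fish groups and 2 diets) of 4 libraries each, 48 libraries in all. RNA was extracted with a column kit and libraries were made by a sequencing centre, per the labels.

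The deposited values were raw fragment counts per gene, 1 file per library with 69389 genes each. Per the file headers, the authors counted reverse-stranded read pairs over exons grouped by gene with featureCounts from an Ensembl-style annotation of the Ssal_v3.1 assembly, on alignments in which duplicates had been marked and not removed. Reads mapping to several places or overlapping several genes were not counted, so recent gene duplicates, frequent in the salmon genome, lose reads to each other. The submitters named Subread version 1.5.1. The aligner and its version were not given in the sources used here. The header lines of 5 distal intestine files (fish SW-91 of the A LAN6 group and all 4 fish of the B LAN6 group) pointed to another processing folder than the rest. Whether the reads of these files were otherwise processed in the same way is unknown. Head kidney and liver libraries carried 1 lane label and distal intestine libraries another, so lane did not vary within a tissue.

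The number after SW in each library title was taken here as the fish number, though the labels do not say so, and fish are named by it (SW-1 and so on). Group A control held fish SW-1, SW-2, SW-19 and SW-20, A LAN6 fish SW-55, SW-56, SW-91 and SW-92, B control fish SW-43, SW-44, SW-79 and SW-80, and B LAN6 fish SW-97, SW-98, SW-103 and SW-104. In the distal intestine fish SW-57 and SW-45 stood in place of fish SW-56 and SW-44, so that 14 numbers were shared by all 3 tissues. Nothing in the labels says that the libraries of a group came from separate tanks or even that they are separate animals beyond these numbers, so p-values measure the spread between these samples.

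Count files carry Ensembl identifiers only. Symbols were taken from a reference table of 65341 genes on the same assembly by overlap of their spans on the same chromosome, since the table gives no strand. Of the genes in the count files 25756 were matched, 22795 with an overlap of at least 0.8 and 2961 with an overlap of 0.5 to 0.8 and no other candidate. Of these 7554 carried a symbol other than a LOC number. Shifting all coordinates by 200 kb left 429 and 721 matches in these classes. The table has no product names, so gene lists were filled by symbol alone, and paralogs known only by LOC numbers are missing from them.

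Each tissue was analysed separately in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per fish group and diet was tested by F tests with Benjamini-Hochberg adjustment at 0.05. The diet contrast was the mean of the LAN6 minus control differences in fish groups A and B. Further contrasts were diet within each fish group, the difference between these diet effects, and fish group B minus A averaged over diets. A test with 12 means over the 48 libraries asked whether the diet effect was equal in the 3 tissues. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Levels are CPM, the usual count scaled to the library total times its TMM factor, as mean ± SD over 4 libraries, and log2 CPM per library used a prior count of 2. All tests are two-sided unless stated. How many fish lay in the direction of a change was counted against the mean of the fish it was compared with, control fish of the own fish group for diet and A fish on the same diet for fish group.

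Of the 39 gene lists fixed for immune functions, cell types, metabolism and stress, 35 had at least 5 members among the counted genes. Lists with at least 5 measured genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists. The gene counts adjusted over the list alone used the same edgeR p-values. Another 25 immune genes were to be reported whatever their values. The genes named in the text follow a rule. Among genes past the threshold with a symbol, the rule takes the 10 smallest p-values in each direction, and where none passes the 5 smallest, given as not passing. It adds up to 4 members with the smallest p-values of each called list, and the immune genes. The contrasts, tests, lists, naming rule and all alternatives but 1 were chosen before the data were examined.

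The alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, limma-voom with quality weights, no filter, a filter of 1 CPM in 8 libraries, each library left out in turn, counts of neighbouring fish summed to 2 units per group, an additive model, and only the 8 libraries of a fish group for its own contrast. Lists were also tested with an estimated correlation and with fry, and diet by tissue with the fish number as a block. A fit of diet by tissue without a pair of libraries that stood apart was chosen after the data were seen. The splits of the samples were all 35 splits of 8 libraries, 100 for 16 libraries with labels exchanged within fish groups or within diets, and 40 for diet by tissue, the real split included.

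The methods were tested on simulated negative binomial counts at the depths, mean levels and dispersions of these libraries, with 200 genes changed. For diet edgeR recovered 61.2% of folds of 2 in head kidney, 62.7% in liver and 35.8% in distal intestine. For folds of 1.5 these were 13.4%, 16.4% and 3%. Within 1 fish group at most 31.3% of folds of 2 were recovered, and at most 3% as a difference between fish groups' diet effects. False calls made up 1.8%, 1.8% and 7.1% of edgeR's calls in the 3 tissues, 28%, 17.2% and 23.5% of DESeq2's, and 2.9%, 1% and 4.8% of voom's. Camera called a list shifted by 0.5 log2 units in all 3 tissues, and 1 unshifted list in head kidney. Genes were drawn uncorrelated, so this decides nothing for real lists.

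Depth was 17673682 to 31777211 counted fragments per library in head kidney, 10122524 to 26517219 in liver and 5676514 to 31003591 in distal intestine. The number of genes tested was 30293, 25686 and 30351. The root of the common dispersion, which measures the spread between fish beyond counting error, was 0.33, 0.29 and 0.38, so that fish and not depth set most of the error for all but weakly expressed genes. The in vitro work and the pathogen challenge named in the series title were not analysed here.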

Results

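The series asked how a diet with hydrolyzed yeast changes gene expression in Atlantic salmon after transfer to seawater. RNA was counted in 16 libraries each of head kidney, the main blood-forming and immune organ of fish, of liver and of distal intestine. Every combination of tissue, fish group (A or B) and diet (control or LAN6, the yeast diet) held 4 libraries. Libraries held 5676514 to 31777211 counted fragments. Per library 27140 to 30767 genes reached 10 counts in head kidney, 21787 to 26502 in liver and 17552 to 31515 in distal intestine. The marker lists matched the labels. The mean level of the hepatocyte list was 10.51 to 11.17 log2 CPM in liver libraries and at most 1.06 in the others. The enterocyte list lay at 6 to 6.98 in distal intestine, and the leukocyte list at 4.36 to 4.77 in head kidney. Libraries are named by tissue and fish number. Log2 fold changes are LAN6 minus control or B minus A.

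The head kidney comparison asked whether diet changed expression in an immune organ. Of genes with a symbol mmp13 and ezrb had the smallest p-values, neither passing. The collagenase gene mmp13 (ENSSSAG00000070495, chromosome 4, 53644674 to 53651276) stood at 1150 ± 235.1 CPM (SD, n = 4) in A control and 1580 ± 254 in A LAN6. In fish group B it stood at 798 ± 138 in B control and 1670 in B LAN6 (10.46 to 10.89 as log2 CPM over the 4 fish). Its log2 fold change was 0.77 (SE 0.14, adjusted p = 0.286). For ezrb (ENSSSAG00000110492, chromosome 15, 29222202 to 29291025), a member of the ezrin family that links membrane and actin, the levels were 26.5 ± 3.57, 39.5 ± 3.03, 33.3 ± 7.8 and 51.8 ± 5.78 CPM in the same order. The log2 fold change was 0.61 (SE 0.11, adjusted p = 0.286). The gelatinase gene mmp9 (ENSSSAG00000069874, chromosome 15, 101635200 to 101645091), abundant in granulocytes, stood at 1980 ± 264, 2690 ± 390, 1320 ± 591 and 2150 ± 599 CPM. The log2 fold change was 0.57 (SE 0.21, adjusted p = 0.641). All 8 LAN6 fish lay above their control mean for each of these 3 genes. The same held for tmem245 (0.59, SE 0.12), ap4b1 (0.65, SE 0.14) and ints6l (0.46, SE 0.11), whose smallest adjusted p was 0.618. For mmp9 LAN6 fish SW-104 (10.41 log2 CPM) lay below B control fish SW-43 (10.63) and SW-80 (10.98). Fish SW-79 (9.58) lowered the B control mean. Fish SW-91 lay below control fish SW-20 for both mmp genes. Of 30293 genes tested, edgeR called 0 for diet, with 2089 at an unadjusted p under 0.05, while DESeq2 called 40 and limma-voom 0. Leaving out fish SW-56 gave 2 calls in edgeR and leaving out fish SW-80 gave 1.

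Among the gene lists in head kidney, all 30 ribosomal protein genes and all 31 respiratory chain genes were lower with LAN6, with median log2 fold changes of -0.53 (adjusted p = 3.93e-08) and -0.46 (adjusted p = 4.78e-06) by camera. These values went with fish SW-79 of the B control group, whose ribosomal list stood 1.87 log2 units and whose respiratory list 1.73 above the tissue median. Without fish SW-79 the medians were -0.11 (adjusted p = 0.00218) and -0.03 (adjusted p = 0.307). Examples were rps12 at -0.68 (SE 0.32), rplp1 at -0.6 (SE 0.29), sdhc at -0.49 (SE 0.24) and ndufv1 at -0.23 (SE 0.11). The 5 genes of bile acid and xenobiotic metabolism were also lower, with a median of -0.4 (adjusted p = 0.0169, 7 of 8 fish). Among them were the transporter genes abcc2 at -0.58 (SE 0.3) and slc51a at -0.48 (SE 0.21) and the enzyme genes gstt1a at -0.4 (SE 0.2) and cyp7b1 at -0.22 (SE 0.14). The extracellular matrix list was higher, with a median of 0.13 over 15 genes, 11 of them higher (adjusted p = 0.00753, 7 of 8 fish), including mmp13, mmp9, col6a2 at 0.51 (SE 0.24) and col6a1 at 0.46 (SE 0.21). The ribosomal list was lower in 6 of 8 fish and the respiratory list in 7 of 8. For each of these 4 lists the adjusted p = 0.679 with an estimated correlation. The matrix list lost its call without fish SW-56 or fish SW-103, and its median ran from 0.09 to 0.17 over the 16 fits that left out 1 library. Adjusted over the list alone, 1 matrix gene (mmp13) passed, and none in the other 3 lists, against 0 over all genes tested.

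The immune lists of head kidney did not pass with all libraries. The proinflammatory list had a median of 0.13 over 7 genes (adjusted p = 0.143), with mmp13 and mmp9 as the 2 genes that passed when adjusted over the list alone. Without fish SW-79 it passed, at 0.1 (adjusted p = 0.0184), as did granulocyte markers at 0.18 (adjusted p = 0.0184), glycolysis at 0.13 (adjusted p = 0.0408) and erythroid markers at -0.18 (adjusted p = 0.019). The list of acute phase and iron genes, products of liver for the most part, had a median of 2.07 (adjusted p = 0.143), with 5 of 7 genes passing when adjusted over the list alone (smallest adjusted p there 0.048). Its median without fish SW-79 was 1.98 (adjusted p = 0.0406), and it also passed without fish SW-56, SW-91 or SW-98. The LAN6 libraries of fish SW-55 and SW-104 held more hepatocyte transcripts than the other 14 libraries. The mean of 13 hepatocyte genes was 0.99 log2 CPM in fish SW-55 and 0.78 in fish SW-104, against -2.01 to -0.53, and their acute phase lists stood at 1.81 and 1.47, against at most 0.47. Without fish SW-55 the acute phase median was 0.93 (adjusted p = 0.371) and without fish SW-104 it was 1.49 (adjusted p = 0.262), so a diet effect was not separated from liver RNA in these 2 libraries. Hepatocyte markers had a median of 1.33 (adjusted p = 0.277), with 3 genes passing when adjusted over the list alone (smallest adjusted p there 0.0354). In the fits that left out 1 library the hepatocyte median was 0.32 to 0.81 where 9 genes were kept by the filter and 1.4 to 1.49 where the same number as with all libraries, 8, was kept, and the list passed without fish SW-98 (0.71, adjusted p = 0.0317). Skeletal muscle markers had a median of 2.4 (adjusted p = 0.153), which was 0.77 (adjusted p = 0.731) without fish SW-97, and the list passed without fish SW-56, SW-98 or SW-104 (2.59 to 2.6). Of the 25 immune genes set out to be reported, 11 were measured in head kidney, with log2 fold changes from -0.27 to 0.57 and a smallest adjusted p of 0.641. Among them il8 stood at 0.2 (SE 0.5), mx2 at 0.28 (SE 0.51), tgfb1a at 0.16 (SE 0.27), cd8a at -0.27 (SE 0.27) and hamp at -0.19 (SE 0.55).

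**Figure D1:**
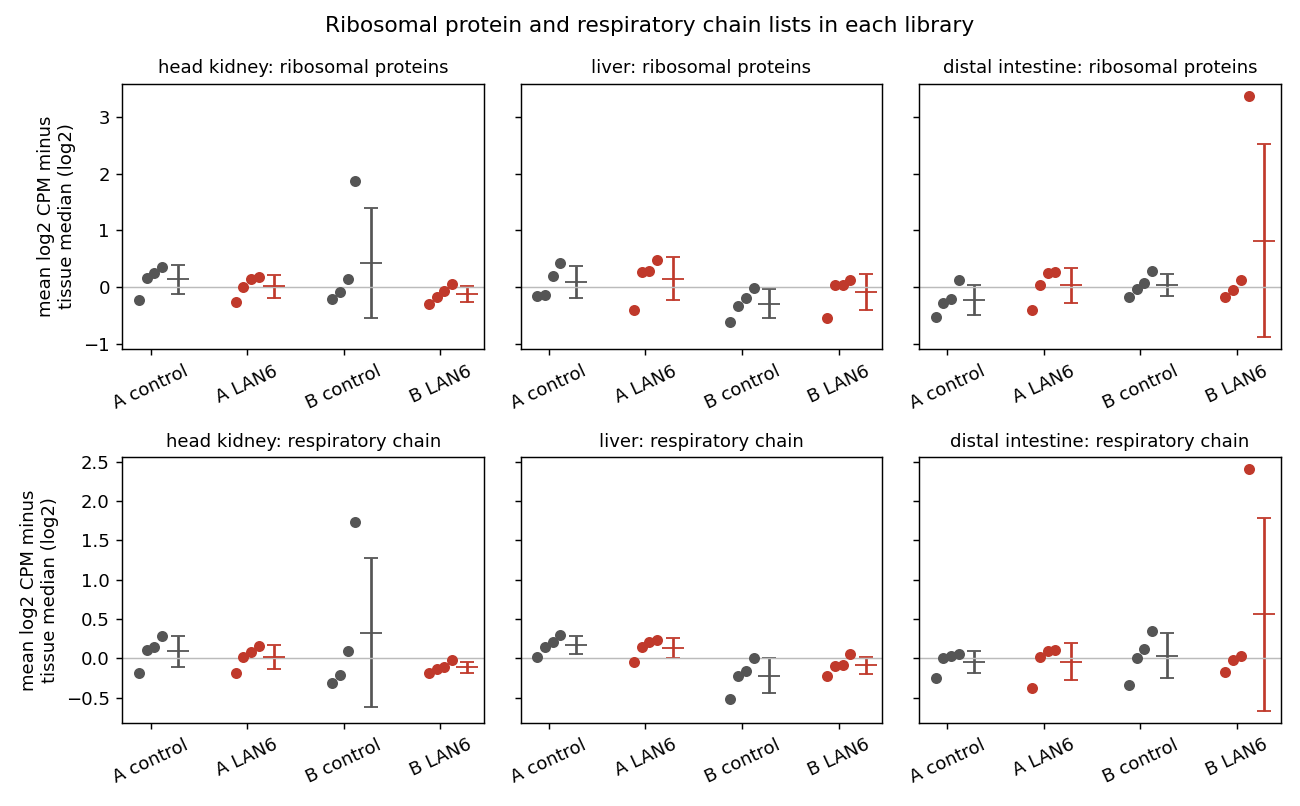
Mean log2 CPM of the ribosomal protein genes (top) and respiratory chain genes (bottom) in each library minus the median of its tissue, by tissue and group, with the mean and SD of each group of 4 libraries. Head kidney fish SW-79 (B control) stood at 1.87 for the ribosomal list and distal intestine fish SW-104 (B LAN6) at 3.37.

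Within fish group A, the 6 interrenal and chromaffin genes of head kidney, which make catecholamines and steroids, were all higher with LAN6 (median 0.45, adjusted p = 0.0362, 4 of 4 fish). Among them chga stood at 0.68 (SE 0.65), pnmt at 0.51 (SE 0.53) and th at 0.4 (SE 0.45). The mean of the interrenal list was 0.57 and 1.36 log2 CPM in A control fish SW-1 and SW-2. It was 4.45 and 3.64 in A control fish SW-19 and SW-20, against 2.92 to 4.63 in the A LAN6 fish. A diet effect on the interrenal list was therefore not separated from the make-up of the tissue pieces. The bile acid and xenobiotic list was lower (median -0.28, adjusted p = 0.0362, 3 of 4 fish), and for both lists the adjusted p = 0.651 with an estimated correlation. The interrenal call was lost without fish SW-1, SW-2, SW-56, SW-79 or SW-91, with medians from 0.13 to 1.11 over the fits that left out 1 library, and the bile acid call without fish SW-2, SW-20, SW-55, SW-91 or SW-92, with medians from -0.42 to -0.16. Within fish group B, mmp13 had the largest diet difference of the named genes of the matrix list, 1.07 (SE 0.19, adjusted p = 0.585, 4 of 4 fish), beside mmp9 at 0.71 (SE 0.29). The matrix list was higher (median 0.15, adjusted p = 0.00111, 14 of 15 genes, 1 passing when adjusted over the list alone). Ribosomal and respiratory genes were lower, with medians of -0.89 (adjusted p = 1.52e-10) and -0.8 (adjusted p = 1.23e-08), all 30 and all 31 of them, and without fish SW-79 the medians were -0.09 and 0 and neither was called. For these 3 lists the adjusted p = 0.749 with an estimated correlation, and the matrix call was lost without fish SW-103, with medians from 0.09 to 0.27. In fish group B the skeletal muscle list had a median of 4.35 (adjusted p = 0.106), with 6 of 10 genes passing when adjusted over the list alone, and fish SW-97 stood at 4.22 log2 CPM for it, against -0.91 to 1.99 in the other 3 B LAN6 fish.

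Neither fish group gave a diet call in head kidney by edgeR. In fish group A 745 genes had an unadjusted p under 0.05 (DESeq2 29 calls, voom 1) and in group B 2383 (DESeq2 30, voom 0). The genes with a symbol and the smallest p-values in A included nrgnb at -3.11 (SE 0.77), ezrb at 0.58 and ap4b1 at 0.71, all with an adjusted p of 1. In B they included mc6zb at 0.82 (SE 0.16), rund1 at -1.77 (SE 0.43), gaa at 0.6 (SE 0.15) and ezrb at 0.64 (SE 0.16), all with an adjusted p of 0.585. Without fish SW-56 or fish SW-79 group A gave 1 call, and without fish SW-44 group B gave 2. The test of the difference between the diet effects gave 0 calls by edgeR, 23 by DESeq2 and 0 by voom, with 615 genes at an unadjusted p under 0.05. Its smallest p-value among genes with a symbol was that of nrgnb, which stood at 1.8 ± 1.08 and 0.204 ± 0.196 CPM in A control and A LAN6 and at 0.306 ± 0.076 and 1.87 ± 1.15 in B control and B LAN6 (difference 5.7, SE 1.06, adjusted p = 0.8). The next was mc6zb (1.17, SE 0.23, adjusted p = 0.8). Without fish SW-20, SW-56 or SW-79 this test gave 1 call.

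Fish groups A and B differed in head kidney by 12 genes, 9 higher and 3 lower in B. The only called gene with a symbol was bbs7 (ENSSSAG00000004055, chromosome 5, 26369365 to 26375534), which encodes a part of the BBSome, a complex of ciliary transport. It rose from 2.13 ± 0.267 and 2.42 ± 0.582 CPM in A control and A LAN6 to 4.52 ± 0.424 and 4.45 ± 0.711 in B control and B LAN6 (log2 fold change 0.98, SE 0.14, adjusted p = 0.0145, 8 of 8 fish). The 11 genes of the type I interferon list were all higher in B (median 0.29, adjusted p = 0.0148, 6 of 8 fish). Examples were cmpk2 at 1.11 (SE 0.33, adjusted p = 0.514, 8 of 8 fish), mx2 at 1.07 (SE 0.52), rtp3 at 0.65 (SE 0.42) and irf3 at 0.3 (SE 0.19). Of these cmpk2 passed when adjusted over the list alone. The matrix list was lower (median -0.11, 11 of 15 genes, adjusted p = 0.0425, 5 of 8 fish), with acta2 at -0.43 (SE 0.14) and mmp9 at -0.45 (SE 0.21), and for both lists the adjusted p = 0.67 with an estimated correlation. Without fish SW-79 the interferon median was 0.31 (adjusted p = 0.00288). Respiratory genes (-0.18, adjusted p = 8.24e-11), ribosomal genes (-0.18, adjusted p = 4.59e-07), proteasome genes (-0.17, adjusted p = 0.000801) and B and plasma cell markers (0.28, adjusted p = 0.0256) also passed. DESeq2 called 144 genes, the 12 among them, and voom 40, with 9 of the 12, while 1595 genes had an unadjusted p under 0.05.

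The head kidney counts between fish groups moved with the fish in the fit. There were 29 calls without fish SW-79, 7 without fish SW-43 or SW-80, 6 without fish SW-98, 5 without fish SW-1, 4 without fish SW-20 or SW-91, and 3 without fish SW-55. Summing neighbouring fish gave 23 calls, with 7 of the 12 among them. The call of bbs7 was lost without fish SW-1, SW-20, SW-55 or SW-91, with log2 fold changes between 0.93 and 1.07 over all such fits, and with neighbouring fish summed (0.97). The interferon list lost its call without fish SW-19, SW-56, SW-80 or SW-104 (medians 0.21, 0.19, 0.15 and 0.1), and the matrix list without fish SW-1, SW-20, SW-56, SW-79, SW-98 or SW-104, with medians from -0.18 to -0.05, and with neighbouring fish summed (-0.1).

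In liver, the same question was asked of the main metabolic organ. All 8 LAN6 livers lay above the control mean of their fish group for both metalloproteinase genes, neither of which passed the threshold. Single fish overlapped. As log2 CPM, LAN6 fish SW-55 stood at 0.38 for mmp13, below control fish SW-2 (0.49) and SW-19 (0.8). For mmp9, LAN6 fish SW-103 (1.53) and SW-104 (1.26) stood below control fish SW-79 (1.6) and SW-80 (1.94). Both genes were highest in fish SW-98 (2.49 and 2.94), whose liver library held pancreas transcripts. The level of mmp13 was 1.15 ± 0.403 and 2.03 ± 0.561 CPM in A control and A LAN6 and 1.36 ± 0.335 and 3.32 ± 1.51 in B control and B LAN6 (log2 fold change 1.04, SE 0.24, adjusted p = 0.513). That of mmp9 was 1.51 ± 0.12, 3.07 ± 1.49, 2.26 ± 1.3 and 4.31 ± 2.38 CPM (0.96, SE 0.31, adjusted p = 0.513). The uridine phosphorylase gene upp2 (chromosome 25, 12408793 to 12411404) stood at 74.2 ± 50.2, 162.9 ± 112, 27.7 ± 4.81 and 149 ± 102 CPM (1.78, SE 0.39, adjusted p = 0.513, 8 of 8 fish). The level of emid1 (ENSSSAG00000054756, chromosome 20) was 4.11 ± 0.407, 2.65 ± 0.585, 5.38 ± 0.628 and 3.83 ± 0.161 CPM (-0.56, SE 0.12, adjusted p = 0.513, lower in 8 of 8 fish). Other genes with a symbol and small p-values were nsun4 at 0.54 (SE 0.12) and pxdc1b at -0.45 (SE 0.1). Of 25686 genes tested edgeR called 0 for diet, with 2232 at an unadjusted p under 0.05, DESeq2 called 16 and voom 1. Without fish SW-20 there were 2 calls and without fish SW-56 there was 1.

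**Figure D2:**
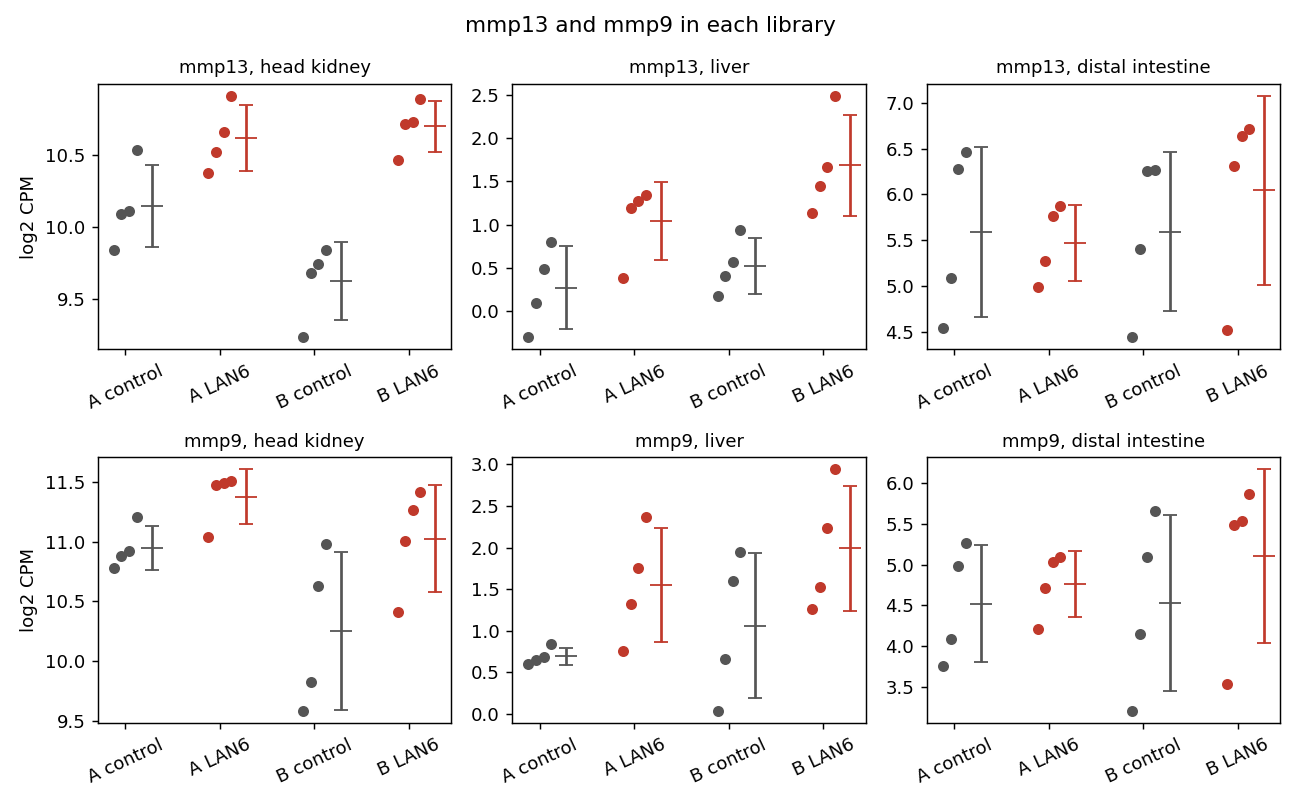
Log2 CPM of mmp13 and mmp9 per library, with group mean and SD (n = 4). In head kidney and liver all 8 LAN6 fish lay above their control mean for both genes. In distal intestine mmp13 differed by 0.11 (SE 0.35, adjusted p = 0.981) and mmp9 by 0.35 (SE 0.36, adjusted p = 0.94). There fish SW-104 (4.52 and 3.53) lay below the other B LAN6 fish (from 6.31 and 5.49).

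The 4 liver lists past camera's threshold for diet had small medians. All 7 acute phase and iron genes were higher (median 0.18, adjusted p = 0.0172, 6 of 8 fish). Among them hp, which encodes the haemoglobin scavenger haptoglobin, stood at 2570 ± 986, 4180 ± 1890, 2080 ± 691 and 3740 ± 2510 CPM in A control, A LAN6, B control and B LAN6 (0.77, SE 0.3, adjusted p = 0.522, 7 of 8 fish), and the hemopexin genes hpxa at 0.4 (SE 0.21) and hpxb at 0.38 (SE 0.19). Cell cycle genes were lower (median -0.19, 17 of 22 genes, adjusted p = 0.0172, 7 of 8 fish), with ccna2 at -0.51 (SE 0.19), birc5a at -0.48 (SE 0.19), ccnb1 at -0.45 (SE 0.19) and cenpe at -0.34 (SE 0.18). Ribosomal genes were higher (median 0.15, 26 of 30 genes, adjusted p = 0.0172, 6 of 8 fish), as were renal tubule and endothelium markers (median 0.31, 10 of 11 genes, adjusted p = 0.0292, 6 of 8 fish). Of the latter, the scavenger receptor genes stab2 at 0.6 (SE 0.26) and stab1 at 0.45 (SE 0.16) and the endothelial gene plvapb at 0.64 (SE 0.28) stood higher and the tubule gene lrp2a lower at -0.84 (SE 0.47). With an estimated correlation the adjusted p = 0.902 for the ribosomal list and the adjusted p = 0.719 for the other 3. No gene of these 4 lists passed when adjusted over the list alone. The calls depended on the fish in the fit. That of the acute phase list was lost without fish SW-2, SW-20, SW-43, SW-79, SW-97 or SW-103 (medians 0.14 to 0.49), and that of the cell cycle list without fish SW-2, SW-79, SW-91, SW-97 or SW-98 (-0.24 to -0.11). The ribosomal call was lost without fish SW-2, SW-20, SW-43, SW-55, SW-92, SW-103 or SW-104 (0.07 to 0.21), and the renal and endothelium call without fish SW-1, SW-2, SW-19, SW-56, SW-79, SW-91, SW-92, SW-97 or SW-103 (0.15 to 0.41). With neighbouring fish summed the cell cycle (-0.2) and endothelium (0.3) lists lost their calls.

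Further liver lists did not pass as lists but held genes that passed for diet when adjusted over the list alone. These were 2 proinflammatory genes, mmp13 and mmp9 (list median 0.1, adjusted p = 0.121), and mmp13 again in the matrix list (0.16, adjusted p = 0.208). In the erythroid list 3 genes rose and 1 fell (0.19, adjusted p = 0.208). The others were 2 genes of the glucocorticoid and clock list (-0.08, adjusted p = 0.983), and 1 gene each of the hepatocyte (0.13, adjusted p = 0.208), type I interferon (-0.05, adjusted p = 0.923) and interferon gamma lists (-0.15, adjusted p = 0.844). Of the 25 immune genes, 6 were measured in liver, with log2 fold changes from -0.44 to 0.96, where mmp9 alone had an unadjusted p under 0.05.

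Within fish group A, edgeR called 0 liver genes and camera 0 lists, with 2 lists without fish SW-1 and 1 without fish SW-55, SW-56, SW-91, SW-97 or SW-98. In this contrast 1301 genes had an unadjusted p under 0.05, DESeq2 called 25 and voom 1. The smallest p-values of genes with a symbol included lrrc58b at -1.04 (SE 0.26, adjusted p = 0.829) and gla, a lysosomal galactosidase gene, at -0.55 (SE 0.14). Calls appeared without fish SW-20 (6), fish SW-79 (5), and fish SW-19, SW-55 or SW-56 (1 each).

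Within fish group B, 1 liver gene fell with LAN6, LOC106587701 (ENSSSAG00000008406, chromosome 26, 35022813 to 35033503), chosen after its values were seen because it has a LOC number only. Its level was 14.5 ± 3.18 CPM in B control and 3.49 ± 1.47 in B LAN6, against 4.74 ± 1.45 and 4.72 ± 0.743 in A control and A LAN6 (log2 fold change -2.06, SE 0.28, adjusted p = 0.037, 4 of 4 fish). DESeq2, with 13 calls, and voom, with 1, also called it. The adjusted p was 0.208 when only the B libraries were fitted, the call was lost with neighbouring fish summed, and the edgeR call stayed only in the fits without fish SW-19, SW-20 or SW-97, with log2 fold changes from -2.34 to -1.85. In this contrast 1529 genes had an unadjusted p under 0.05. Heat shock and unfolded protein response genes were higher (median 0.24, 12 of 13 genes, adjusted p = 0.0102, 4 of 4 fish; adjusted p = 0.453 with an estimated correlation), with the endoplasmic reticulum genes herpud1 at 0.71 (SE 0.25) and sdf2l1 at 0.56 (SE 0.19). Hepatocyte markers (median 0.23, 10 of 13 genes, adjusted p = 0.043), ribosomal genes (0.24, 28 of 30, adjusted p = 0.00681), respiratory genes (0.15, 23 of 30, adjusted p = 0.043) and renal and endothelium markers (0.2, 9 of 11, adjusted p = 0.0438) were higher. Cell cycle genes were lower (-0.19, 16 of 22, adjusted p = 0.0283). For these 5 lists the adjusted p = 0.778 with an estimated correlation. Among the hepatocyte genes tat stood at 1.44 (SE 0.5) and apoa1 at 1.17 (SE 0.5).

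Each of these B group list calls in liver was lost without some of the fish. The heat shock call was lost without fish SW-44 (medians 0.21 to 0.3 over the fits). The ribosomal call was lost without fish SW-43, SW-103 or SW-104 (0.14 to 0.33) and the hepatocyte call without fish SW-43, SW-79, SW-103 or SW-104 (0.17 to 0.32). The respiratory call was lost without fish SW-43, SW-80, SW-103 or SW-104 (0.04 to 0.23) and the cell cycle call without fish SW-79, SW-80, SW-97 or SW-98 (-0.3 to -0.06). The renal and endothelium call was lost without fish SW-44, SW-56, SW-79, SW-97 or SW-103 (0.14 to 0.35). With neighbouring fish summed the cell cycle, respiratory and renal and endothelium calls were lost (-0.19, 0.15 and 0.21). The diet effects of the fish groups were not shown to differ in liver, where the test of the difference gave 0 calls by edgeR, 9 by DESeq2 and 2 by voom, with 817 genes at an unadjusted p under 0.05. Its smallest p-values among genes with a symbol were those of ass1, a urea cycle gene, at 2.58 (SE 0.66), hacd3 at 0.9 (SE 0.23) and st8sia4 at -1.66 (SE 0.44), with adjusted p = 1 for ass1. Without fish SW-20 this test gave 3 calls, without fish SW-79 it gave 2 and without fish SW-56 it gave 1.

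In liver 24 genes were higher and 21 lower in B than in A. Of the called genes with a symbol col5a2a, a fibrillar collagen gene (ENSSSAG00000057090, chromosome 21, 21176252 to 21241199), rose from 8.43 ± 0.995 and 6.95 ± 1.01 CPM in A control and A LAN6 to 12.2 ± 1.35 and 12.7 ± 3.05 in B control and B LAN6 (0.7, SE 0.12, adjusted p = 0.0296). The other 5 fell. The peroxisomal gene phyh (chromosome 17, 58492245 to 58496806), whose enzyme oxidises phytanic acid, fell from 93.9 ± 11.8 and 84 ± 14.8 CPM to 45.2 ± 12.8 and 39.9 ± 17.3 (-1.06, SE 0.2, adjusted p = 0.0357). The level of tm4sf21a (chromosome 4, 36069039 to 36072086) fell from 128.2 ± 12.1 and 140 ± 18 CPM to 85.6 ± 20.1 and 65.3 ± 11.5 (-0.84, SE 0.13, adjusted p = 0.0151). The others were pias2 at -2.07 (SE 0.36, adjusted p = 0.0316), rhbdd1 at -0.82 (SE 0.15, adjusted p = 0.0319) and itsn1 at -0.65 (SE 0.11, adjusted p = 0.0305). All 8 B fish lay on the same side of the A mean for each of these 6 genes. DESeq2 called 393 genes, all 45 among them, and voom 521, with 39 of the 45, while 3245 genes had an unadjusted p under 0.05.

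As lists, respiratory chain and ribosomal protein genes were lower in B livers. Of 30 respiratory chain genes 28 were lower (median -0.32, adjusted p = 2.02e-12, 8 of 8 fish), and 16 passed when adjusted over the list alone, against none over all genes tested. The cytochrome c oxidase gene cox5b2 stood at 134 ± 21.8 and 145 ± 12.6 CPM in A control and A LAN6 and at 83.2 ± 25.3 and 92.8 ± 14.2 in B control and B LAN6 (-0.67, SE 0.15, adjusted p = 0.0938 over all genes). Others were ndufb5 at -0.55 (SE 0.12), cox6a1 at -0.6 (SE 0.14) and sdhc at -0.34 (SE 0.08). Of 30 ribosomal genes 28 were lower (median -0.3, adjusted p = 1.61e-08, 8 of 8 fish), with rplp1 at -0.43 (SE 0.14) and rps7 at -0.4 (SE 0.12). With an estimated correlation the adjusted p = 0.351 for the respiratory list and the adjusted p = 0.61 for the ribosomal list. The test fry, which asks only whether a list moves 1 way, gave an adjusted p of 0.02 for the respiratory list. Gene length moved with the fish groups as well. The rank correlation of a library's deviation from the liver median with gene length was -0.14 to -0.01 in the 8 A livers, 0.03 to 0.17 in 7 B livers and -0.03 in B fish SW-79. Whether the state of the RNA accounts for the liver lists that differ between fish groups was not tested and stays open.

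Connective tissue lists were higher in B livers. Smooth muscle and fibroblast markers had a median of 0.58 (6 of 7 genes, adjusted p = 0.000539, 7 of 8 fish) and the matrix list 0.15 (11 of 15 genes, adjusted p = 0.0166, 7 of 8 fish). In each, 4 genes passed when adjusted over the list alone. The lists share members, and the named ones were the proteoglycan gene lum at 1.13 (SE 0.29), the fibronectin gene fn1a at 0.74 (SE 0.22) and the collagen genes col6a2 at 0.63 (SE 0.17), col6a1 at 0.58 (SE 0.17) and col1a1a at 0.54 (SE 0.18). All 11 renal and endothelium markers were higher (median 0.27, adjusted p = 0.0142, 8 of 8 fish), with stab1 at 0.42 (SE 0.16). With an estimated correlation the adjusted p = 0.552 for the fibroblast list and the adjusted p = 0.564 for the other 2. The endothelium call was lost without fish SW-55 or SW-97 (median 0.18 in each fit) and the matrix call without fish SW-55, SW-97 or SW-98 (0.1 to 0.29), while the respiratory, ribosomal and fibroblast calls stayed in all 16 such fits. Granulocyte markers were not called (median 0.53, 7 of 7 genes higher, adjusted p = 0.0944), nor erythroid markers (-0.27, 9 of 9 lower, adjusted p = 0.0791).

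The number of genes that differed between fish groups in liver was 15 without fish SW-43 or SW-80, 18 without fish SW-91, 20 without fish SW-55 or SW-92, 24 without fish SW-19 or SW-44, 26 without fish SW-2, SW-97 or SW-98, 27 without fish SW-103 and 29 without fish SW-1. With neighbouring fish summed to 2 units per group it was 24, with 13 of the 45 among them, and none of the 6 named genes was called. The call of tm4sf21a stayed in all 16 fits that left out 1 library. That of col5a2a was lost without fish SW-1, SW-19, SW-43, SW-55, SW-80, SW-91 or SW-97 (log2 fold changes 0.63 to 0.76) and that of itsn1 without fish SW-2, SW-19, SW-43, SW-44, SW-55, SW-80, SW-91, SW-97 or SW-98 (-0.71 to -0.6). Those of the other 3 stayed only without fish SW-2, SW-20, SW-55, SW-56 or SW-97 for pias2 (-2.23 to -1.94), fish SW-20, SW-56, SW-97, SW-98 or SW-103 for rhbdd1 (-0.9 to -0.71), and fish SW-56, SW-79, SW-98, SW-103 or SW-104 for phyh (-1.17 to -0.95).

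In the distal intestine, where the diet meets the gut wall and its immune cells, lipid synthesis genes were lower and granulocyte and proinflammatory genes higher with LAN6, as lists. Of the LAN6 libraries 5 of 8 came from the second processing folder and none of the 8 control libraries did, so the diet contrast of this tissue is partly confounded with the folder. Fatty acid synthesis and desaturation genes had a median of -0.31 (9 of 10 genes, adjusted p = 0.00574, 8 of 8 fish; adjusted p = 0.496 with an estimated correlation). The desaturase gene fadsd6 stood at 200 ± 47.6, 167.8 ± 48.8, 160 ± 30.2 and 111 ± 24.1 CPM in A control, A LAN6, B control and B LAN6 (-0.39, SE 0.18, 7 of 8 fish), beside fadsd5 at -0.43 (SE 0.22) and gpam at -0.46 (SE 0.27). All 9 genes of cholesterol and isoprenoid synthesis were lower (median -0.16, adjusted p = 0.00566, 6 of 8 fish). The regulator of that pathway, srebf2 (chromosome 3, 66658651 to 66672468), stood at 80.3 ± 7.7, 52.9 ± 14.9, 87.1 ± 22.7 and 63.9 ± 25.8 CPM (-0.52, SE 0.21, 7 of 8 fish), beside stard4 at -0.3 (SE 0.15) and hmgcs1 at -0.47 (SE 0.31). All 9 granulocyte markers were higher (median 0.42, adjusted p = 0.00419, 5 of 8 fish), with cxcr2 at 0.61 (SE 0.24) and srgn at 40.2 ± 17.1, 54.8 ± 31.5, 49.6 ± 12.1 and 88.3 ± 55.8 CPM (0.64, SE 0.31). Within groups this list moved with the smooth muscle and fibroblast, renal and endothelium, matrix and B cell lists (r = 0.85 to 0.95), so its change was not separated from the make-up of the tissue pieces. All 9 proinflammatory genes were higher (median 0.27, adjusted p = 0.0244, 6 of 8 fish), with il18 at 0.58 (SE 0.26) and il34 at 0.35 (SE 0.19). Fish SW-45, SW-57 and SW-103 had the highest granulocyte means (4.8 to 4.95 log2 CPM), and fish SW-1, SW-19 and SW-55 the lowest (2.26 to 2.64). Proinflammatory means were 3.16 to 3.33 in the former and 1.53 to 1.92 in the latter, and cholesterol means 4.94 to 5.33 and 5.31 to 5.63. Whether the make-up of the pieces accounts for these lists was not tested. For the cholesterol, granulocyte and proinflammatory lists the adjusted p = 0.533 with an estimated correlation. The fatty acid call was lost without fish SW-45 or SW-97 (medians -0.4 to -0.2 over the fits) and the cholesterol call without fish SW-79 or SW-97 (-0.23 to -0.12). The granulocyte call was lost without fish SW-103 (0.26) and the proinflammatory call without fish SW-1, SW-19, SW-43, SW-57, SW-79, SW-97 or SW-103 (0.06 to 0.5).

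Other intestinal lists moved with LAN6 by camera. Cell cycle genes were lower (median -0.15, 18 of 21 genes, adjusted p = 0.00115, 6 of 8 fish), with cenpe at -0.37 (SE 0.17), bub1 at -0.32 (SE 0.14) and top2a at -0.3 (SE 0.17). Fatty acid oxidation genes were lower (median -0.11, 13 of 16 genes, adjusted p = 0.0212, 7 of 8 fish). Among them cpt1ab, which encodes the entry enzyme of mitochondria for fatty acids, stood at -0.31 (SE 0.16) and etfdh at -0.25 (SE 0.12). The oxidation mean was 5.62 to 5.78 log2 CPM in fish SW-45, SW-57 and SW-103, which were highest in granulocyte markers. It was 5.94 to 6.11 in fish SW-1, SW-19 and SW-55, which were lowest in them. Enterocyte markers were called lower with a median of -0.22 but a mean of 0.02 (10 of 13 genes lower, adjusted p = 0.0212, 6 of 8 fish), with mep1bb at -0.25 (SE 0.14), npc1l1 at -0.29 (SE 0.17) and the peptide transporter gene slc15a1 higher at 1.56 (SE 0.99). For these 3 lists the adjusted p = 0.533 with an estimated correlation. The oxidation call was lost without fish SW-1, SW-19, SW-43, SW-57, SW-97 or SW-103 (medians -0.17 to -0.07) and the enterocyte call without fish SW-1, SW-20, SW-43, SW-92 or SW-97 (-0.28 to -0.13), while the cell cycle call stayed in all 16 fits. No gene of any of these 7 lists passed when adjusted over the list alone.

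Ribosomal genes had a median of 1.07 (29 of 30 genes higher, adjusted p = 8.26e-11, 5 of 8 fish) and respiratory genes 0.61 (27 of 31 higher, adjusted p = 0.00115, 4 of 8 fish) in the intestinal diet contrast. These values went with fish SW-104 of the B LAN6 group, whose ribosomal list stood 3.37 and whose respiratory list 2.4 log2 units above the tissue median. The level of rps12 was 144, 181 and 158 CPM in A control, A LAN6 and B control and 948 ± 1570 in B LAN6. Without fish SW-104 the ribosomal median was 0.11 (adjusted p = 0.00959) and the respiratory median -0.06, not called. The respiratory call was also lost with neighbouring fish summed and fish SW-104 kept (0.14). Without fish SW-104 the fatty acid synthesis median was -0.35 (adjusted p = 0.000896), cholesterol -0.16 (adjusted p = 0.000896), granulocyte 0.51 (adjusted p = 0.00116), proinflammatory 0.28 (adjusted p = 0.00972) and cell cycle -0.11 (adjusted p = 0.000896). The matrix list at 0.25 (adjusted p = 0.00715), renal and endothelium markers at 0.39 (adjusted p = 0.00959) and glycolysis at -0.09 (adjusted p = 0.00987) then passed too. With all libraries and an estimated correlation the adjusted p = 0.533 for the ribosomal and the adjusted p = 0.704 for the respiratory list.

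For single genes of the distal intestine edgeR called 0 of 30351 for diet, with 1241 at an unadjusted p under 0.05, DESeq2 called 13 and voom 0. Among genes with a symbol, small p-values were those of the linker histone gene h1-10 at 0.73 (SE 0.19, 8 of 8 fish), mief2 at 0.93 (SE 0.26), the apoptosis gene bbc3 at 1.1 (SE 0.32), fer1l4 at -1.95 (SE 0.55) and cmbl at -1.09 (SE 0.3), all with adjusted p = 0.94. Without fish SW-20 there was 1 call. The 11 measured immune genes had log2 fold changes from -0.54 to 1.78, none with an unadjusted p under 0.05, and hamp, which encodes the iron hormone hepcidin, stood at 1.78 (SE 1.02).

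**Figure D3:**
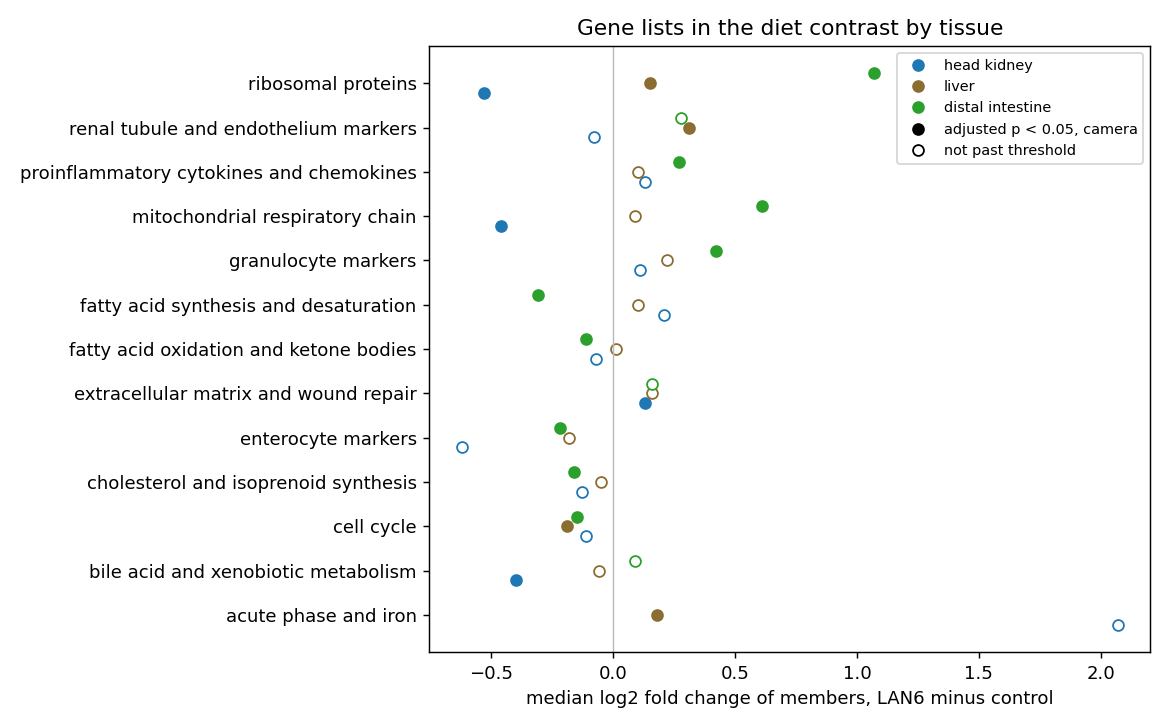
Median log2 fold change of LAN6 minus control over the measured genes of each list in each tissue, with filled points where camera's adjusted p passed the threshold at the preset correlation. The medians of the ribosomal list were -0.53 in head kidney, 0.15 in liver and 1.07 in distal intestine.

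Within fish group A of the distal intestine, enterocyte markers were lower (median -0.37, 11 of 13 genes, adjusted p = 0.00111, 3 of 4 fish). The brush border protease genes stood lower, mep1bb at -0.53 (SE 0.2) and mep1a.2 at -0.52 (SE 0.22) and the glucose transporter gene slc5a1 at -0.49 (SE 0.23). Cholesterol synthesis genes (-0.24, 9 of 9 lower, adjusted p = 0.00111, 4 of 4 fish), fatty acid oxidation genes (-0.21, 14 of 16, adjusted p = 0.00821, 4 of 4 fish) and interferon genes (-0.32, 10 of 12, adjusted p = 0.0153, 3 of 4 fish) were lower too. Among the interferon genes mx2 stood at -1.09 (SE 0.61) and helz2a at -0.82 (SE 0.4). Granulocyte markers (0.51, 9 of 9, adjusted p = 0.0132, 3 of 4 fish) and renal and endothelium markers (0.58, 11 of 12, adjusted p = 0.0091, 3 of 4 fish) were higher, the latter with vwf at 1.6 (SE 0.82) and plvapb at 0.67 (SE 0.32). For these 6 lists the adjusted p = 0.508 with an estimated correlation. The granulocyte, endothelium, cholesterol and oxidation differences of group A were not separated from the make-up of the tissue pieces. The interferon call was lost without fish SW-1, SW-20, SW-55 or SW-92 (medians -0.48 to -0.12), the granulocyte call without fish SW-1, SW-19, SW-57 or SW-91 (0.24 to 0.81). The oxidation call was lost without fish SW-1, SW-19 or SW-57 (-0.28 to -0.16) and the endothelium call without fish SW-19 or SW-91 (0.29 to 0.74). Of single genes edgeR called 0, with 800 at an unadjusted p under 0.05 (1738 without fish SW-104), DESeq2 13 and voom 0. Of genes with a symbol cmbl had the smallest p-value. It stood at 36 ± 26.3 CPM in A control and 7.36 ± 1.14 in A LAN6 (-2.28, SE 0.45, adjusted p = 1), and the next was acpl2 at 1.05 (SE 0.26). Without fish SW-20 there were 3 calls.

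Within fish group B of the distal intestine, cell cycle genes were lower (median -0.33, 18 of 21 genes, adjusted p = 1.84e-06, 4 of 4 fish), with cenpe at -0.71 (SE 0.24), ccnb1 at -0.57 (SE 0.23), mki67 at -0.56 (SE 0.21) and bub1 at -0.54 (SE 0.2). This call stayed in all 16 fits that left out 1 library. Ribosomal genes were higher (1.85, 29 of 30, adjusted p = 8.81e-12, 2 of 4 fish, 27 passing when adjusted over the list alone). So were respiratory genes (1.15, 28 of 31, adjusted p = 2.46e-07, 1 of 4 fish) and antioxidant genes (0.27, 11 of 11, adjusted p = 0.0262, 1 of 4 fish), with gpx4a at 1.96 (SE 0.66) and txnb at 0.9 (SE 0.51). Without fish SW-104 these medians were -0.07, -0.1 and -0.06, and the antioxidant call was also lost without fish SW-79 or SW-80, with medians up to 0.42 over the fits. The respiratory and antioxidant calls were lost with neighbouring fish summed (0.19 and 0.1). The adjusted p = 0.835 with an estimated correlation for the respiratory list and the adjusted p = 0.807 for the other 3. Of single genes edgeR called 0, with 1644 at an unadjusted p under 0.05, DESeq2 5 and voom 0. Genes with a symbol and small p-values included rufy2 at -0.46 (SE 0.13), h1-10 at 0.91 (SE 0.27) and rund1 at -1.84 (SE 0.56), with adjusted p = 0.888. All 4 B LAN6 libraries came from the second processing folder and no B control library did, so folder and diet cannot be told apart in this contrast. The diet effects of the fish groups were not shown to differ in the intestine, with 0 calls by edgeR, 6 by DESeq2 and 0 by voom and 795 genes at an unadjusted p under 0.05. For genes with a symbol the smallest p-values were those of acpl2 at -1.7 (SE 0.37), cmbl at 2.38 (SE 0.61) and mbtps2 at -1.14 (SE 0.3), with adjusted p = 1, and without fish SW-20 there was 1 call.

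Between fish groups the distal intestine gave 6 called genes, 1 higher and 5 lower in B, none with a symbol. DESeq2 called 139 genes, the 6 among them, and voom 42, with 5 of the 6, while 1839 genes had an unadjusted p under 0.05. Fatty acid synthesis genes were lower (median -0.31, 7 of 10 genes, adjusted p = 0.0472, 7 of 8 fish). The regulator of that pathway, srebf1, stood at 41.6 ± 11.8 and 36.8 ± 7.95 CPM in A control and A LAN6 and 28.8 ± 9.27 and 21.4 ± 8.53 in B control and B LAN6 (-0.65, SE 0.23, adjusted p = 0.775, 8 of 8 fish). Other members were gpam at -0.71 (SE 0.27), fadsd6 at -0.46 (SE 0.18) and elovl5 at -1.45 (SE 0.59). Ribosomal genes (1.05, 29 of 30, adjusted p = 1.99e-08, 6 of 8 fish) and respiratory genes (0.77, 28 of 31, adjusted p = 5.4e-05, 6 of 8 fish) were higher, and without fish SW-104 their medians were 0.1 and 0.03 and neither was called. For all 3 lists the adjusted p = 0.818 with an estimated correlation. The fatty acid call was lost without fish SW-19, SW-20, SW-55, SW-79, SW-80, SW-91, SW-97, SW-98 or SW-103 (medians -0.46 to -0.23), and with DESeq2 size factors or the 1 CPM filter (-0.29 in each). The number of called genes was 15 without fish SW-2, 12 without fish SW-80, 11 without fish SW-97, 10 without fish SW-79, 2 without fish SW-43 and 0 without fish SW-103. Summing neighbouring fish again gave 6, of which 1 was the same gene. As 4 of the 8 B libraries and 1 of the 8 A libraries came from the second folder, this contrast is partly confounded with it.

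Several genes that differed between fish groups did so in more than 1 tissue, and 5 were called in both head kidney and liver. They have no symbol and were chosen after their values were seen. ENSSSAG00000086049 fell in B, with log2 fold changes of -6.53 (SE 0.75, adjusted p = 0.00454) in head kidney and -3.94 (SE 0.59, adjusted p = 0.0148) in liver, and stood at -3.17 (SE 0.77, adjusted p = 0.292) in distal intestine. ENSSSAG00000097978, on an unplaced scaffold, rose in all 3 tissues, by 3.41 (SE 0.55), 4.86 (SE 0.79) and 3.85 (SE 0.48), with adjusted p = 0.0419, 0.0214 and 0.0165. ENSSSAG00000104995 on chromosome 7 rose by 1.71 (SE 0.23, adjusted p = 0.012) in head kidney and 2.64 (SE 0.45, adjusted p = 0.0296) in liver and stood at 1.44 (SE 0.24, adjusted p = 0.0666) in distal intestine. ENSSSAG00000087881 (chromosome 24, 41861355 to 41972002) rose by 2.14 (SE 0.34, adjusted p = 0.0419) and 2.05 (SE 0.24, adjusted p = 0.00403) and stood at 1.79 (SE 0.35, adjusted p = 0.146). ENSSSAG00000008831 (chromosome 26, 21597177 to 21626147) rose by 2.16 (SE 0.33, adjusted p = 0.0419) and 2.09 (SE 0.37, adjusted p = 0.0319) and was not tested in the intestine. Of the genes called in liver, 35 of 43 measured had the same sign in head kidney and 33 of 42 in distal intestine. With voom the calls of ENSSSAG00000086049 and of ENSSSAG00000097978 in head kidney and liver were lost. With neighbouring fish summed those of ENSSSAG00000104995 and ENSSSAG00000097978 were lost in both tissues, that of ENSSSAG00000087881 in head kidney and that of ENSSSAG00000008831 in liver.

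The calls of these 5 genes held to different degrees when 1 library was left out. ENSSSAG00000086049 kept its calls in head kidney and liver in all 16 fits, ENSSSAG00000104995 in head kidney and ENSSSAG00000087881 in liver. In head kidney ENSSSAG00000087881 stayed called only without fish SW-19 or SW-79 (log2 fold changes 2 to 2.48), ENSSSAG00000097978 only without fish SW-79 or SW-104 (3.22 to 3.62) and ENSSSAG00000008831 only without fish SW-44, SW-79 or SW-92 (2.01 to 2.32). In liver ENSSSAG00000008831 stayed called only without fish SW-20, SW-97, SW-98 or SW-104 (1.75 to 2.37), ENSSSAG00000104995 lost its call without fish SW-19, SW-43, SW-44, SW-55, SW-80, SW-91, SW-97 or SW-103 (2.44 to 2.92) and ENSSSAG00000097978 without fish SW-55, SW-91 or SW-92 (4.51 to 5.28). In distal intestine ENSSSAG00000097978 lost its call without fish SW-103 (3.69 to 4.02).

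**Figure D4:**
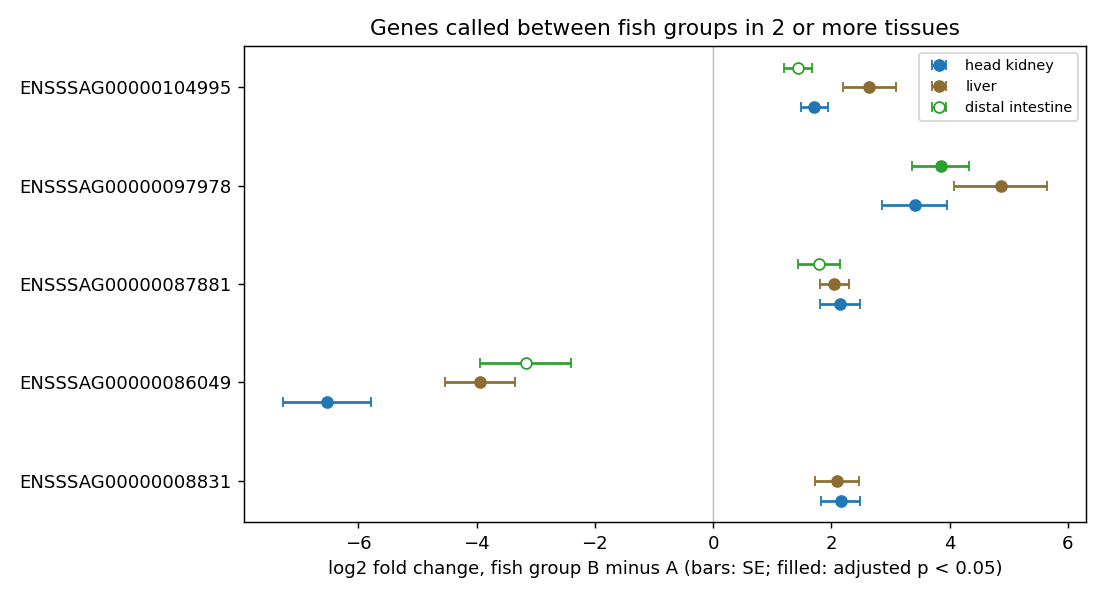
Log2 fold change of fish group B minus A with its standard error for the 5 genes called between fish groups in both head kidney and liver, by tissue. ENSSSAG00000097978 was called in all 3 tissues, at 3.41, 4.86 and 3.85.

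The test of whether the diet effect differed between tissues gave 0 calls by edgeR among 34894 genes, with 2592 at an unadjusted p under 0.05. This fit takes the libraries of a fish as independent, while same-numbered fish correlated between head kidney and liver in all 16 pairs (r = 0.15 to 0.37). With the fish number as a block 4 genes were called (smallest adjusted p = 0.0351), so the count depends on the model. The smallest p-values with a symbol included smad6b, an inhibitor of BMP signalling, whose diet effect was 0.77 larger in liver and 0.84 larger in distal intestine than in head kidney on the log2 scale (adjusted p = 0.298). They also included fam124a (1.73 and 0.97, adjusted p = 0.298), itga8 (-3.04 and 0.29, adjusted p = 0.298) and actn3b, an actinin gene of fast muscle (-3.46 and -3.6, adjusted p = 0.365). The latter 2 values are set against head kidney, where fish SW-97 on LAN6 held muscle transcripts (3.06 log2 CPM over 11 muscle genes, tissue median -0.29). Without fish SW-45 of the intestine there were 40 calls, without fish SW-98 in all tissues 3, and without fish SW-20 or SW-97 there was 1. No list call in any tissue held with an estimated correlation, and fry called 2 lists in the liver fish group contrast and 0 elsewhere. These were the respiratory list and the list of ion transport and seawater osmoregulation, whose median was 0.53 over 5 genes (camera adjusted p = 0.0944), with 3 genes passing when adjusted over the list alone.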

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

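The fits without head kidney fish SW-79 or intestine fish SW-104 as tests of the ribosomal lists, the tests of depth and of RNA from other tissues in head kidney fish SW-79, the shared signs between liver and intestine, and the correlation of granulocyte and stroma lists were chosen after the result was seen. The other tests were written down before their results.

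The ribosomal and respiratory lists moved with diet in opposite directions in head kidney and distal intestine, and each tissue held 1 library that stood far from the rest, head kidney fish SW-79 and intestine fish SW-104. Without them the ribosomal medians went from -0.53 to -0.11 and from 1.07 to 0.11, so most of the diet difference in these lists came with the 2 libraries. Low depth is argued against, since fish SW-79 had 24106238 counts, rank 13 of 16 from the lowest, and fish SW-104 reached 10 counts in 17552 genes where the other intestine libraries thinned to its total reached at least 22417. RNA of hepatocytes, enterocytes, pancreas or skeletal muscle in fish SW-79 is argued against too, as no such list lay above the highest other head kidney library (largest margin -0.58, enterocyte markers), while renal tubule RNA was not tested. Fish SW-79 did stand above the other B control fish in hepatocyte markers, but fish SW-55 and SW-104, which had more of them, stood only 0.17 and 0.05 above the tissue median for the ribosomal list. The deviations of both libraries from their tissues correlated across 27111 genes at r = 0.65, against at most 0.41 for the other pairings (genes are not independent replicates), which is consistent with a state of the RNA shared by both (rho of the deviation with gene length was -0.45 and -0.25, the lowest of each tissue), while a shared response of the animals was not tested.

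Genes that differed between fish groups recurred between tissues. Deviations of same-numbered fish from their group means in head kidney and liver correlated at r = 0.56 over the 47 genes that were tested in both tissues and called between fish groups in either, with at most 0.45 among the other pairings, which is consistent with differences between individual fish carried in every tissue. A batch within the libraries of 1 tissue could not be excluded for all genes, since 78.6% of those called in liver (33 of 42) had the same sign in the intestine. What A and B stand for is not given, so a genetic difference between families, a tank or another origin stays open and was not tested.

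In the distal intestine the leukocyte and connective tissue lists varied together between fish of the same group. Over 16 libraries as deviations from their group means, the granulocyte list correlated with smooth muscle and fibroblast markers at r = 0.85 (permutation p = 0.00067, adjusted p = 0.00067 over 4 relations, rho = 0.91 with permutation p = 0.00024), with renal and endothelium markers at 0.86 (permutation p = 0.00036, rho = 0.81 with permutation p = 0.00072), with the matrix list at 0.9 (permutation p = 4e-05, rho = 0.86 with permutation p = 7e-05) and with B and plasma cell markers at 0.95 (permutation p = 3e-05, rho = 0.94 with permutation p = 3e-05), all one-sided and with adjusted p of at most 0.00072. Without the farthest fish SW-45 and SW-2 r was 0.82, 0.82, 0.88 and 0.95, and without fish SW-104 it was 0.85, 0.92, 0.92 and 0.96. The share of wall layers in each tissue piece may have differed between fish, and gut inflammation that varies between fish would give the same values, so the higher granulocyte list with LAN6 stays open between these and a diet effect. The split of the intestine with 861 genes, against 0 for the real diets, put fish SW-1, SW-19, SW-43, SW-55, SW-79, SW-80, SW-92 and SW-104 against fish SW-2, SW-20, SW-45, SW-57, SW-91, SW-97, SW-98 and SW-103, with 4 of the 5 libraries of the second folder on the latter side, and points to a structure of these samples other than diet, which was not tested further.

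Within groups of 4 libraries, 13 sets of values held a library far from the other 3. These were 8.6% of the sets tested, where chance alone gives about 1 in 20, or 7.6 sets. Head kidney fish SW-79 stood at 10.45 log2 CPM for the ribosomal list (others 8.37 to 8.72) and at 1.07 for the 8 hepatocyte markers kept by the filter (0.27 to 0.38 in the other B control fish, 2.98 and 2.68 in fish SW-55 and SW-104). Intestine fish SW-104 stood at 10.8 for the ribosomal list (7.26 to 7.56), at 8.16 for the respiratory list (5.59 to 5.79) and at 3.53 for mmp9 (5.49 to 5.87). Head kidney fish SW-55 had 40643 genes detected (39057 to 39295) and an acute phase level of 1.81 (-1.3 to -0.95). Head kidney fish SW-91 had a TMM factor of 1.11 (1.01 to 1.02) and an mmp9 level of 11.04 (11.48 to 11.51). Liver fish SW-98 stood at 7.05 for the ribosomal list (7.64 to 7.73) and liver fish SW-55 at 0.38 for mmp13 (1.19 to 1.34). Intestine fish SW-20 stood at 5.51 for the respiratory list (5.76 to 5.81) and intestine fish SW-103 at 7.59 for enterocyte markers (7.07 to 7.12).

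The splits exchange single fish. The gene counts between fish groups stood at 12 in head kidney (highest other split 2), 45 in liver (highest other 4) and 6 in distal intestine (highest other 0), each reached by 1 of 100 splits, so chance can be excluded for them if the fish are independent. Neighbouring fish or tanks were not kept together in these splits. With neighbouring fish summed 7 of the 12, 13 of the 45 and 1 of the 6 genes were called again, and the intestinal count was 0 without fish SW-103. For diet within fish group B the real count in liver was 1 (5 of 35 splits, highest other 2), and chance could not be excluded. Where the real count was 0 every split gave as many by construction, so the comparison decides nothing about chance. This holds for diet (100 of 100 splits in each tissue, highest other 35 in head kidney, 3 in liver and 861 in distal intestine) and for the difference between diet effects (100 of 100, highest other 2, 39 and 2). It holds for diet within fish group A (35 of 35, highest other 8, 52 and 2), within fish group B in head kidney and distal intestine (35 of 35, highest other 2 and 1) and for diet by tissue (40 of 40, highest other 7). Single splits with 35, 52, 39 and 861 genes, where the real splits gave 0, point to structure among the fish that the groups do not describe, which was not tested.

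The counts of called lists gave no better separation. For diet, head kidney had 4 lists (87 of 100 splits gave as many, highest other 15), liver 4 (40 of 100, highest other 8) and distal intestine 9 (20 of 100, highest other 14). Within fish group A the counts were 2 (29 of 35 splits, highest other 10), 0 (35 of 35, highest other 7) and 6 (16 of 35, highest other 15) in the same order of tissues, and within fish group B 3 (34 of 35, highest other 13), 6 (12 of 35, highest other 11) and 4 (23 of 35, highest other 11). Between fish groups they were 2 (100 of 100 splits, highest other 11), 5 (32 of 100, highest other 11) and 3 (84 of 100, highest other 15). Chance could not be excluded for any of these list counts above 0, and the count of 0 in liver group A decides nothing.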

How the results depend on the processing

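Only the fit of diet by tissue without head kidney fish SW-79 and intestine fish SW-104 was chosen after the data were seen, and it gave 0 calls, as with all libraries. Of the counts per comparison, 98 stayed within 1.5 times the reported one under the other alternatives and 68 did not, and of 450 counts in the fits that left out 1 library 327 stayed and 27.3% did not. For 260 followed values of genes and lists, 1452 results kept direction and side of the threshold. In 191 only the direction stayed, 26 gained a call and 2 reversed. Without 1 library these numbers were 3542, 611, 1 and 6. Most lists that passed only without 1 fish lie outside this set. Causes of changes were not tested. Depth limits weak genes most, folds of 1.5 mostly went undetected, and fewer folds of 2 were recovered in the intestine.

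With the DESeq2 Wald test the counts of head kidney were 40 for diet, 29 in fish group A, 30 in B, 23 for their difference and 144 between fish groups, those of liver 16, 25, 13, 9 and 393, and those of distal intestine 13, 13, 5, 6 and 139. On simulated data at least 17.2% of its calls were false. With voom they were 1 in head kidney group A and 40 between fish groups, in liver 1 for diet, 1 in group A, 2 for the difference and 521 between fish groups, and 42 between fish groups in distal intestine. With only the libraries of that fish group 2 genes were called in head kidney A and 0 in liver B. With neighbouring fish summed, head kidney gave 1 gene in B and 23 between fish groups, and liver 2 for diet, 10 in A, 3 for the difference and 24 between fish groups. The list counts were then 7 for diet, 8 in A, 5 in B and 1 between fish groups in head kidney, 1 in A and 3 in B in liver, and 14 for diet, 7 in B and 5 between fish groups in distal intestine. Without a filter there were 20 genes between fish groups in head kidney and 4 in liver group A. With 1 CPM in 8 libraries there were 3 genes between fish groups in head kidney, and the list counts were 0 in A and 4 between fish groups in head kidney and 1 in A in liver. With an estimated correlation 0 lists were called in every contrast, and with fry 0 in all but the liver fish group contrast with 2. Blocking on the fish number gave 4 genes for diet by tissue. The number pairs tissues plausibly, as deviations of same-numbered fish correlated at 0.15 to 0.37 between head kidney and liver, at -0.1 to 0.4 between head kidney and intestine and at -0.11 to 0.34 between liver and intestine. The cause of these differences was not tested.

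Leaving out 1 library gave these lowest and highest gene counts for diet, fish group A, fish group B, their difference and fish group. They were 0 to 2, 0 to 1, 0 to 2, 0 to 1 and 3 to 29 in head kidney, 0 to 2, 0 to 6, 0 to 1, 0 to 3 and 15 to 62 in liver, and 0 to 1, 0 to 3, 0 to 0, 0 to 1 and 0 to 15 in distal intestine. The list counts for diet, A, B and fish group were 3 to 9, 0 to 7, 3 to 5 and 0 to 8 in head kidney, 0 to 5, 0 to 2, 2 to 6 and 3 to 7 in liver, and 4 to 11, 3 to 10, 2 to 7 and 1 to 7 in distal intestine. Lists for diet in head kidney were 9 without fish SW-104, 8 without fish SW-79 and 7 without fish SW-98, in liver 0 without fish SW-2, 1 without fish SW-79 or SW-103 and 2 without fish SW-20, SW-43, SW-91, SW-92 or SW-97, and in distal intestine 4 without fish SW-97. Diet by tissue ran from 0 to 40, the latter without fish SW-45. Signs reversed without head kidney fish SW-79 for the respiratory list in group B (0), and without intestine fish SW-104 for the respiratory list for diet (-0.06) and in group B (-0.1), and in group B for antioxidant genes (-0.06), ribosomal genes (-0.07) and txnb (-0.27), and with voom for txnb (-0.16) and ndufa7 (-0.03) in group B. Over the fits without 1 library these values reached -1.05 for the respiratory list of head kidney group B, 0.74 for that of the intestine for diet, and in intestine group B 1.44 for respiratory, 0.42 for antioxidant and 2.18 for ribosomal genes and 1.21 for txnb. Voom gave fish SW-79 of head kidney a weight of 0.07 and fish SW-104 of the intestine 0.12, the lowest of each tissue, and the causes of the reversals were not tested.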

Other observations

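The tests of the metalloproteinase genes between tissues and of the second processing folder were written down before their results, and the other values were chosen after they were seen.

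Some libraries held transcripts of neighbouring organs. The mean level of 3 exocrine pancreas genes was 9.73 log2 CPM in liver fish SW-98, against a median of 0.06 over the 16 liver libraries and a lowest value of -2.93. The mean of 11 skeletal muscle genes was 3.06 in head kidney fish SW-97, against a median of -0.29 and a lowest value of -1.57. That of 13 hepatocyte genes was 0.99 and 0.78 in head kidney LAN6 fish SW-55 and SW-104, against a median of -1.11. In liver, the ion transporter gene slc12a2 stood at 0.53 (SE 0.2, edgeR adjusted p = 0.29) in B minus A.

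Some of the liver genes called between fish groups lie beside each other. On chromosome 6 ENSSSAG00000086049 (51135799 to 51176409) stood at -3.94 and ENSSSAG00000107130 (51141236 to 51146441), within its span, at -1.86. On chromosome 26 ENSSSAG00000008831 (21597177 to 21626147) stood at 2.09 and ENSSSAG00000109353 (21576513 to 21585493) at 3.01. On chromosome 2 LOC106592607 (9545825 to 9559847) stood at 2.36 and LOC106606090 (9499238 to 9515169) at 1.79. ENSSSAG00000097978 and ENSSSAG00000084471 lie on the same unplaced scaffold and stood at 4.86 and 3.36.

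A hypothesis was that mmp13 and mmp9 may respond in the whole animal, so that fish with more of them in head kidney would have more in liver. Over 16 fish as deviations from group means, mmp13 gave r = -0.2 (one-sided permutation p = 0.764, rho = -0.21 with permutation p = 0.765) and mmp9 r = 0.35 (permutation p = 0.158, adjusted p = 0.316, rho = 0.25 with permutation p = 0.222). Without the 2 farthest fish r was -0.11 and 0.42. A value of -0.2 over 16 fish lies within the spread of no relation, so the bound set beforehand was too tight to exclude a weak relation, and the hypothesis was not borne out.

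A further hypothesis was that the second processing folder could account for the diet difference of group B in the intestine. The deviation of A LAN6 fish SW-91, the only A library from that folder, correlated with that difference across genes at 0.02, against 0.11, 0.05 and -0.17 for the other 3 A LAN6 fish. This rests on 1 library, and the folder coincides with B LAN6, so the bound set beforehand cannot exclude the folder.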
